A study of Mus musculus with 12 samples.

How the data were processed

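Gene expression was measured in MECs, a mouse endothelial cell line of embryonic origin, on 12 two-colour Agilent oligonucleotide arrays. The 12 arrays fell into 4 groups of 3: mock-treated control cells and cells treated for 4, 12 or 24 h with BMP6, a growth factor of the TGF-beta superfamily. Groups and replicate numbers were taken from the sample titles. Per the labels, each group held independent biological replicates, RNA of the cells carried Cy5, and a universal mouse reference RNA carried Cy3.

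The deposited values, taken here as log2 ratios of the 2 channels, were normalized by the authors with a modified local quantiles method before deposit, per the labels. The base of the log and the sign are not given in the sources used here. They were read as cells over reference, from the dyes in the labels. If they ran the other way, every rise given here would be a fall and every fall a rise, levels and ranks of lists would turn, and total counts and adjusted p-values would be the same. If the base were the natural logarithm, every fold given here would be larger, while tests and adjusted p-values would be the same. Each array held 20280 values, none missing, with a mean of 0. The array medians lay between -0.04 and 0.002 and the SDs between 0.607 and 0.688. Correlations between arrays ran from 0.877 to 0.980, and the closest pair of arrays differed by a median of 0.061, so no array was a copy of another. No spot intensities or backgrounds were used here, so no statement is made on whether a probe was detected, and the number of arrays limits the precision.

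Gene names came from an annotation table of the platform that lists 11083 probe numbers: 10576 with 1 symbol, covering 8267 genes, and 507 with several symbols, from which no gene was named. The other 9197 value rows carry no name here. Symbols were updated through gene identifiers for 10548 probes, and 28 kept their old name. At the deposited row numbers, the first 2 probes of a gene did not correlate across genes (Pearson r = 0.021 over 1831 genes, which are not independent replicates). The 20280 rows are part of a grid of 22575 positions. Reading that grid in 14 orders gave r = 0.471 in a single one, which reads it along the other side from the opposite corner, and at most 0.068 in each of the rest. On single arrays that order gave r from 0.397 to 0.496. All 11083 listed probe numbers then fell on a position with a value, where chance placement would leave 1126.7 without one and the 12 orders other than this and the deposited one filled 89.71% to 90.83%. The deposited order fills all positions by construction, because the table lists only probe numbers present among the rows. Shifting the row numbers by up to 3000 positions, in 6000 trials, gave r between -0.104 and 0.093. The recovered order was therefore used for every gene name. It was chosen after seeing the data, on agreement between probes of a gene and not on treatment effects, although treatment effects in the deposited order had been seen by then. Under it, 2097 rows have a probe number that the table could not list. Counts of probes do not depend on the order, and every named gene does.

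Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 over the 20280 probes. One fit over the 12 arrays gave the contrasts of 4, 12 and 24 h against control, the contrasts between times, and an F test over the 3 contrasts against control. This fit is called unpaired below. Gene values come from the same fit on the average of a gene's probes, so a gene can pass in one and miss in the other. The 3 comparisons with control share the same 3 control arrays, and the labels give the controls no time.

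Replicate numbers 1 to 3 recur in each group, and the pairing was checked on each array's deviations from its group mean. All 18 correlations between same-numbered arrays of different groups were positive, from 0.443 to 0.695, and those between differently numbered arrays ran from -0.564 to 0.069. By a rule fixed beforehand (every correlation of a pair above 0.1) the numbers pair the samples. The pairing comes from the numbers in the titles alone, since no label says what same-numbered arrays share. These correlations and the counts of both fits were seen at the same time. Replicate numbers held 54.07% of the sum of squares, treatment groups 20.56%, and 25.37% was left. A fit with the replicate number as an additive block, called paired below, is given beside the unpaired fit: at 4 h it called 548 probes against 20.

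Both fits were tested on simulated data, in which 50 probes each were changed by a log2 value of 0.5, 1, 1.5 or 2 in the 20280 probes. In the 4 h comparison the unpaired fit recovered 36% of changes of 0.5 and 94% of changes of 1, with 0 false calls. The paired fit recovered 88% and 100%, with 15 false calls among 209. The simulated arrays were built from the paired model, with its replicate effects and independent noise of its variance. The gain of the paired fit was therefore built in, and the simulation does not test the pairing.

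Before the data were examined, 25 gene lists were fixed, of which 400 genes were measured and 18 sat in more than 1 list. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 75 tests (25 lists at 3 times). The same test with the correlation estimated from the data stands beside it; fry, which tests whether genes of a list move on balance one way, is given for each list that passed it. The rule for naming genes was fixed at the same time. It took, at each time, up to 10 genes per direction with the largest change among those that passed (probes of a gene averaged, 1 symbol per probe, unannotated clones and expressed sequence names left unnamed) with all treated arrays on one side of the control arrays. Where fewer than 5 passed, the list was filled to 5 by unadjusted p. It added 15 genes named whatever their result, of which Smad6, Smad7 and Ptgs1 were not measured here, and up to 4 members of each list with the smallest p in the F test. Further members of lists are named because they passed in the paired fit, a choice made after their values were seen, as are some of the genes behind counts of 20 or fewer. Applying the rule to the paired fit, with a change in one direction in all 3 pairs, was a choice made after seeing the data.

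Alternatives chosen at the same time were the replicate block, quantile normalization between arrays, centring each array on its median, array weights, eBayes with a trend and robust variance, a minimum change of 1.5-fold, averaging a gene's probes, fitting only the groups compared, leaving out each array, the methods' t-test, and an estimated correlation for the lists. Added after seeing the data were the deposited row order for gene names and the same alternatives for the paired fit, with the 4 arrays of each replicate number left out in turn, and each array left out of the paired list tests, of fry and of the probes behind counts of 20 or fewer.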

Results

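Expression was profiled in mouse MEC endothelial cells given a mock treatment or BMP6 for 4, 12 or 24 h, with 3 arrays per group and 12 in all. The series title names cyclooxygenase 2 and prostanoid production in the response to BMP6, and the comparisons ask which transcripts differ from control at each time and between times. Values are log ratios of the cells to a common reference RNA, taken as log2 and as cells over reference (neither the base nor the sign is stated). With the opposite sign every rise and fall below would turn. Gene names rest on a reordering of the array positions that was inferred from the data.

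**Figure D1:**
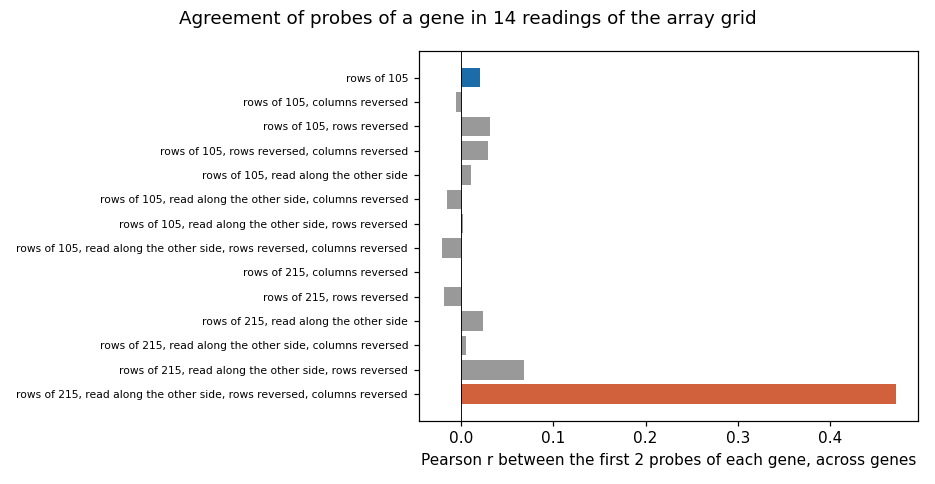
Pearson correlation between the first 2 probes of each gene, across genes (horizontal axis, no unit), for 14 ways of reading the grid of spots (vertical axis). The deposited order (blue) gave 0.021 and the order used here (orange) gave 0.471, with at most 0.068 in the others (grey).

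Relative to the reference RNA, genes of the unfolded protein response lay highest among the 25 lists, with a median of 1.62 over 14 measured members (-1.62 and lowest if the ratios ran the other way), followed by DNA replication and cell division genes at 1.03 over 34. Markers of liver, testis and brain lay lowest at -1.61 (SD over arrays 0.156, 10 members), or highest at 1.61 with the sign turned. Blood cell markers lay at -0.70 over 8 members and epithelial markers at -0.90 over 9. Endothelial identity genes had been predicted to lie above the array median and did not: their median was -0.88, about as low as that of epithelial markers, and 2 of 13 members lay above 0. Markers of blood, liver, testis and brain had been predicted to lie below the array median, and did with the ratios read as cells over reference. The prediction thus held in part. The levels therefore do not settle the sign. Pecam1 had a control level of -1.42 ± 0.241 and Cdh5 of -1.62 ± 0.084 (SD, n = 3).

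After 4 h of BMP6, the secreted signal Wnt2 rose 2.66-fold (log2 change 1.41, SE 0.18, n = 3 per group, adjusted p 0.018 unpaired, 0.00112 paired). Ptgs2, which encodes cyclooxygenase 2, rose 2.54-fold, from a level of 2.99 ± 0.46 (SD, n = 3) in controls (log2 change 1.35, SE 0.192, adjusted p 0.0391 unpaired, 0.00505 paired), and was higher in 3 of 3 pairs. Tnfrsf12a, the receptor of the cytokine TWEAK, rose 2.20-fold and the EGF receptor ligand Hbegf 1.97-fold. Cavin2, a component of caveolae, fell by 1.28 on the log2 scale (SE 0.125, adjusted p 0.00353 unpaired). Hmga2, Il1rap, Adarb1 and Prkcd also rose in the unpaired fit, with log2 changes of 0.94, 0.88, 0.49 and 0.48. Among lower genes, those with the smallest unadjusted p after Cavin2 did not pass: Sema3c at -0.62, Arhgap18 at -0.53, Kat2b at -0.36 and Pmp22 at -0.69. Among probes, the 3 lower calls were those of Cavin2, Sema3c (adjusted p 0.0472) and Bcl9l at -0.51 (0.0222), the last named after its value was seen. The Sema3c probe missed the threshold without control replicate 1 or 2 (0.154 and 0.212), 4 h replicate 1, 2 or 3 (0.102, 0.23 and 0.219), 12 h replicate 1, 2 or 3 (0.0708, 0.0765 and 0.0639) or 24 h replicate 1, 2 or 3 (0.0985, 0.0806 and 0.0855). That of Bcl9l missed it without control replicate 1 or 2 (0.123 and 0.0944) or 4 h replicate 2 or 3 (0.198 and 0.154). The unpaired calls of Tnfrsf12a, Hbegf and Cavin2 passed without each array in turn. With 1 array left out at a time, the unpaired adjusted p missed the threshold for Wnt2 without control replicate 1 or 2 (0.12 and 0.136) or 4 h replicate 3 (0.0747), and for Ptgs2 without control replicate 1 or 2 (0.141 and 0.227), 4 h replicate 2 or 3 (0.257 and 0.215), 12 h replicate 1 or 3 (0.0655 and 0.0623) or 24 h replicate 1, 2 or 3 (0.0726, 0.0799 and 0.0694). It missed for Hmga2 without control replicate 1, 2 or 3 (0.141, 0.243 and 0.101), 4 h replicate 2 or 3 (0.257 and 0.226), 12 h replicate 1 or 3 (0.0719 and 0.0651) or 24 h replicate 1, 2 or 3 (0.0764, 0.0967 and 0.0825). It also missed for Il1rap without control replicate 1 or 2 (0.141 and 0.227), 4 h replicate 2 or 3 (0.289 and 0.218), 12 h replicate 1, 2 or 3 (0.0685, 0.0624 and 0.0651) or 24 h replicate 1 or 2 (0.0726 and 0.0799), and for Adarb1 without control replicate 1, 2 or 3 (0.141, 0.191 and 0.0577), 4 h replicate 1, 2 or 3 (0.0685, 0.257 and 0.119), 12 h replicate 3 (0.0635) or 24 h replicate 1, 2 or 3 (0.0703, 0.0743 and 0.0694). For Prkcd it missed without control replicate 1, 2 or 3 (0.141, 0.227 and 0.0561), 4 h replicate 1, 2 or 3 (0.0685, 0.315 and 0.218), 12 h replicate 3 (0.0746) or 24 h replicate 1, 2 or 3 (0.0732, 0.087 and 0.0825). Under quantile normalization, Ptgs2, Hmga2, Il1rap and Prkcd missed the unpaired threshold (adjusted p 0.0513, 0.0789, 0.0663 and 0.0503), while Txnrd1 at 0.67 passed it (0.0314). On centred arrays Prkcd missed it too (0.0561) and Sema3c passed it (0.0443). With 1 array left out, none of the genes called unpaired at 4 h changed sign. The Ptgs2 change was 1.208 and 1.222 without control replicates 1 and 2 and 1.613 without control replicate 3. It stayed at 1.347 without the 12 h or 24 h arrays that ended its call.

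In the paired fit at 4 h, the matricellular factor Ccn2 rose with a log2 change of 1.37 (paired SE 0.201, adjusted p 0.00898; 0.0571 unpaired). Its probe passed among probes in the unpaired fit (adjusted p 0.0472), and missed the threshold without control replicate 1, 2 or 3 (0.154, 0.226 and 0.0985), 4 h replicate 1, 2 or 3 (0.0893, 0.278 and 0.0756), 12 h replicate 3 (0.0761) or 24 h replicate 1, 2 or 3 (0.0985, 0.09 and 0.0867). The BMP-responsive genes Id1, Id2 and Id3 rose by 0.97, 0.84 and 0.64 (adjusted p 0.00166, 0.0143 and 0.00514), as did the transcription factor Snai1 by 0.79 (0.00653). Their unpaired adjusted p-values were 0.322, 0.471, 0.436 and 0.108. Among the genes that fell in the paired fit were the metalloproteases Adamts5 at -1.35 and Adamts1 at -0.81, the guidance factor Sema3a at -0.91, the retinoblastoma family member Rbl2 at -0.67, Pmp22 at -0.69 and the transcription factor Tef at -0.71. Armcx2, Armcx3 and Armcx6, all on chromosome X, fell as well, by 0.84, 0.74 and 0.66 on the log2 scale. The Armcx2 value had a paired SE of 0.059 and an adjusted p of 0.000755. Of 58 genes named by rule with a paired call at 4 h, 34 passed without each array in turn. Without all 4 arrays of replicate 1, 2 or 3, the paired fit called 314, 0 and 44 probes at 4 h, against 548. Id2 missed the paired threshold with 1 array left out at a time, without control replicate 2 (0.081) or 4 h replicate 2 (0.0568). Tef missed it without control replicate 2 or 3 (0.0833 and 0.0667) or 4 h replicate 2 or 3 (0.0657 and 0.0804).

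Of 20280 probes, 20 passed at 4 h in the unpaired fit, 17 higher and 3 lower, and all 20 were among the 548 that passed in the paired fit, 222 higher and 326 lower. An unadjusted p under 0.05 was reached by 1110 probes, where chance gives 1014, and the methods' t-test called 864 unadjusted and 0 after adjustment. The unpaired count was 3 without control replicate 2 or 4 h replicate 3, 4 without control replicate 1 or 4 h replicate 2, 9 without 24 h replicate 1 or 2, 10 without 24 h replicate 3, 12 without 12 h replicate 3 and 13 without 12 h replicate 1; the paired count was 138, 149 and 188 without control replicate 2, 4 h replicate 3 and 4 h replicate 2, 357 without 12 h replicate 3 and 358 without 24 h replicate 3.

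**Figure D2:**
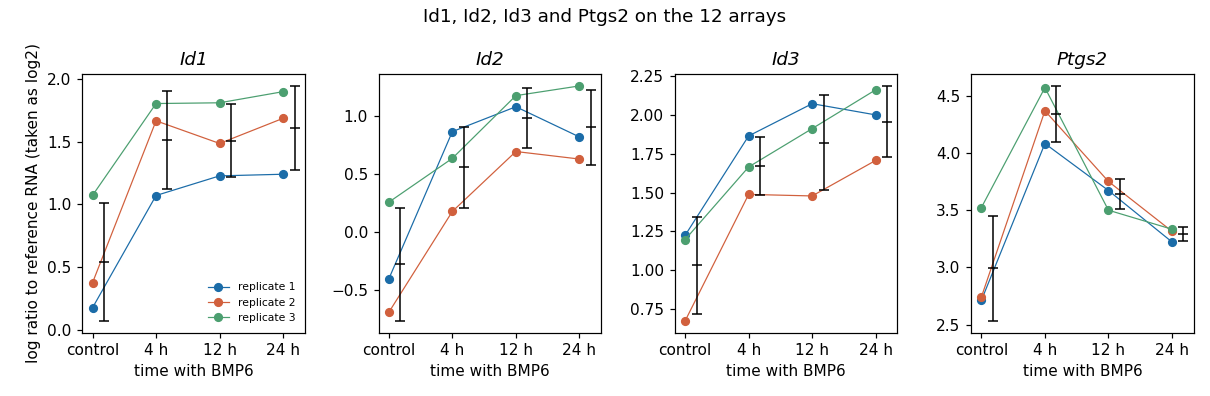
Log ratio to reference RNA, taken as log2 (vertical axis), of Id1, Id2, Id3 and Ptgs2 in controls and after 4, 12 and 24 h of BMP6 (horizontal axis). Points are single arrays, lines join arrays with the same replicate number, and bars show the group mean ± SD (n = 3). Id1 was higher than in the same-numbered control in 3 of 3 pairs at each time.

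At 4 h the BMP target genes lay higher as a group: 14 of 15 measured members were above control, with a mean log2 change of 0.27 and a median of 0.111. In the paired fit 4 of the 15 rose and 0 fell, and adjusted over the list alone 4 rose in each fit. The list passed camera at a preset correlation (adjusted p 0.000382) but not with an estimated one (adjusted p = 0.159 with an estimated correlation, 0.273 paired). Prostanoid genes had a mean of 0.17 (median 0.07) over 12 members, of which Ptgs2 and the prostacyclin synthase Ptgis rose in the paired fit, Ptgis by 0.46 (adjusted p 0.00573). Adjusted over the list alone, 1 rose unpaired, and 2 rose and 1 fell paired. The prostanoid list had an adjusted p of 0.0216 at the preset correlation and an adjusted p = 0.197 with an estimated correlation. Ptges, the prostaglandin E synthase, stood at 0.07 (paired adjusted p 0.663). The BMP target list passed without each array in turn. The prostanoid list missed the threshold without control replicate 1 or 2 (0.0669 and 0.101) or 4 h replicate 1 (0.0846).

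Immediate early genes averaged 0.18 higher at 4 h over 17 members, with a median of 0.111 (camera adjusted p 0.00306; adjusted p = 0.159 with an estimated correlation). In the paired fit 4 of them rose, among them Dusp6 by 0.71 and Myc by 0.32. Smooth muscle and contractile genes averaged 0.15 higher (median 0.089) over 15 members, and the adhesion proteins Vcl and Actn1 rose in the paired fit by 0.77 and 0.48 (list adjusted p 0.00685; adjusted p = 0.304 with an estimated correlation). Heat shock and oxidative stress genes averaged 0.12 higher (median 0.033) over 19 members, with Hmox1, Txnrd1 and Srxn1 rising in the paired fit by 0.65, 0.67 and 0.41 (0.00895; adjusted p = 0.464 with an estimated correlation). Cytokine and adhesion genes averaged 0.10 higher over 15 members, of which Tnfaip3 rose in the paired fit by 0.43 (0.00677; adjusted p = 0.197 with an estimated correlation). BMP and TGF-beta ligands, receptors and mediators averaged 0.07 over 26 members, of which Inhba, Tgfb1 and Acvr1 rose in the paired fit by 0.67, 0.45 and 0.32. That list passed unpaired (0.0433; adjusted p = 0.197 with an estimated correlation), but not paired (0.0725) or after quantile normalization (0.106). The immediate early list missed the threshold without control replicate 1 (0.0587). The smooth muscle list missed the threshold without control replicate 2 (0.149) or 4 h replicate 1 (0.242). The heat shock list missed the threshold without control replicate 1 or 2 (0.249 and 0.153). The cytokine list missed the threshold without control replicate 1 (0.0766). The BMP and TGF-beta mediator list missed the threshold without control replicate 1, 2 or 3 (0.0674, 0.0798 and 0.277), 4 h replicate 1 or 2 (0.138 and 0.104) or 12 h replicate 1 or 2 (0.052 and 0.0536). Acvr1 missed the paired threshold, with 1 array left out at a time, without control replicate 2 (0.052). Inhba missed it without control replicate 2 (0.0831) or 4 h replicate 2 or 3 (0.0915 and 0.104). Myc missed it without control replicate 2 (0.0758) or 4 h replicate 2 or 3 (0.0685 and 0.0651). Txnrd1 missed it without control replicate 2 (0.052) or 4 h replicate 2 or 3 (0.0552 and 0.0561). Tnfaip3 missed it without control replicate 1 or 2 (0.0622 and 0.134) or 4 h replicate 1, 2 or 3 (0.0655, 0.0741 and 0.064). Smooth muscle genes averaged 0.086 without 4 h replicate 1. Heat shock genes averaged 0.067 without control replicate 1, 0.074 without control replicate 2 and 0.216 without control replicate 3. Cytokine genes averaged 0.06 without control replicate 1. BMP and TGF-beta mediators averaged 0.044 without control replicate 3.

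Fibroblast and mesenchymal markers averaged -0.20 at 4 h over 9 members, and Prrx1 and Cdh11 fell in the paired fit, by 0.49 and 0.44 on the log2 scale (list adjusted p 0.00511; adjusted p = 0.353 with an estimated correlation). Cholesterol synthesis genes averaged -0.14 over 12 members, of which Dhcr7 fell in the paired fit by 0.53 (0.00685; adjusted p = 0.506 with an estimated correlation). Glycolysis and hypoxia genes averaged -0.10 over 17 members, with Hk2 higher by 0.35 and Tpi1 lower at -0.54 in the paired fit (0.0444; adjusted p = 0.224 with an estimated correlation), and the list missed the threshold on centred arrays (0.0566). Cell division genes averaged -0.10 over 34 members and oxidative phosphorylation genes -0.12 over 24, with no member of either passing alone (0.00677 and 0.0108; adjusted p = 0.661 with an estimated correlation for each). Ribosomal protein genes averaged -0.16 over 17 members (0.0225; adjusted p = 0.661 with an estimated correlation), and missed the threshold after quantile normalization (0.073). Without control replicate 3 the ribosomal and oxidative phosphorylation means were 0.07 and 0.02 in the unpaired fit, and -0.034 and -0.042 in the paired fit, where the sign did not turn (adjusted p 0.396 and 0.215). Without 4 h replicate 3 the paired means were -0.018 and -0.046 (0.696 and 0.108). The fibroblast list missed the threshold without control replicate 1 (0.0867) or 4 h replicate 3 (0.0959). The cholesterol list missed the threshold without control replicate 2 or 3 (0.227 and 0.0711) or 4 h replicate 1 (0.169). The glycolysis list missed the threshold without control replicate 1, 2 or 3 (0.0867, 0.0938 and 0.222) or 4 h replicate 1, 2 or 3 (0.117, 0.0586 and 0.0874). The cell division list missed the threshold without control replicate 1 or 3 (0.0861 and 0.193) or 4 h replicate 2 or 3 (0.423 and 0.122). The oxidative phosphorylation list missed the threshold without control replicate 1 or 3 (0.0733 and 0.901) or 4 h replicate 2 (0.277). The ribosomal list missed the threshold without control replicate 1 or 3 (0.0535 and 0.551) or 4 h replicate 2 (0.277). Prrx1 missed the paired threshold, with 1 array left out at a time, without control replicate 2 (0.0961) or 4 h replicate 2 or 3 (0.0893 and 0.0708). Cdh11 missed it without control replicate 1, 2 or 3 (0.0751, 0.133 and 0.156), 4 h replicate 2 or 3 (0.152 and 0.129), 12 h replicate 1, 2 or 3 (0.0718, 0.0778 and 0.0803) or 24 h replicate 1, 2 or 3 (0.0562, 0.0799 and 0.0749). Dhcr7 missed it without control replicate 2 or 3 (0.0931 and 0.0722) or 4 h replicate 2 or 3 (0.0701 and 0.0808). Hk2 missed it without control replicate 2 (0.0902) or 4 h replicate 2 or 3 (0.0851 and 0.0746). Tpi1 missed it without control replicate 2 or 3 (0.117 and 0.113), 4 h replicate 2 or 3 (0.12 and 0.108), 12 h replicate 1, 2 or 3 (0.0601, 0.0617 and 0.0669) or 24 h replicate 1, 2 or 3 (0.0571, 0.0634 and 0.0667). Fibroblast markers averaged -0.113 without control replicate 1, -0.328 without 4 h replicate 1 and -0.103 without 4 h replicate 3. Cholesterol genes averaged -0.223 without control replicate 1, -0.081 without control replicate 2 and -0.087 without 4 h replicate 1. Glycolysis genes averaged -0.059 without control replicate 3. Cell division genes averaged -0.165 without control replicate 2, -0.057 without control replicate 3, -0.212 without 4 h replicate 1, -0.028 without 4 h replicate 2 and -0.066 without 4 h replicate 3. Oxidative phosphorylation genes averaged -0.267 without control replicate 2 and -0.046 without 4 h replicate 2. Ribosomal genes averaged -0.354 without control replicate 2 and -0.073 without 4 h replicate 2.

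Adjusted over the list alone in the paired fit at 4 h, 5 immediate early genes and 4 smooth muscle genes rose, while 7 cytokine genes rose and 1 fell. In the heat shock and oxidative stress list 4 rose, among them Hmox1, Txnrd1 and Srxn1. In the same count 5 BMP and TGF-beta mediators rose and 1 fell, 4 fibroblast markers and 6 cholesterol genes fell, 2 glycolysis genes rose and 4 fell, and 0 ribosomal, 0 cell division and 0 oxidative phosphorylation genes passed with limma. The unpaired counts were 2 mediators, 3 cytokine genes, 2 smooth muscle genes and 3 heat shock and oxidative stress genes that rose, 2 fibroblast markers and 1 cholesterol gene that fell, and 0 in the other lists of this count.

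The other 12 lists did not pass at 4 h, with adjusted p from 0.151 for matrix genes to 0.915 for blood cell markers. Mean and median differed in sign for the Wnt list (0.041 and -0.035) and the interferon list (-0.012 and 0.012). Among angiogenic factors Ccn2, Pdgfa and Fgf2 rose and Sema3a and Vegfd fell in the paired fit, with Pdgfa at 0.44 and Vegfd at -0.43 (adjusted over the list alone, 3 rose and 2 fell unpaired, 8 and 5 paired). Within the p53 list Plk2 rose by 0.36 and Sesn1 fell by 0.60 on the log2 scale (adjusted over the list alone, 1 rose and 1 fell in each fit). In the matrix list Timp1, a metalloprotease inhibitor, rose by 0.75 in the paired fit, as did the basement membrane collagens Col4a1 and Col4a2, and Adamts1 fell (adjusted over the list alone, 1 rose and 1 fell unpaired, 8 and 4 paired). Members of the endothelial, Notch, cartilage and bone, blood, epithelial, liver, testis and brain, unfolded protein and interferon lists did not pass over all genes tested in either fit, and Wnt2 alone passed in the Wnt list. Adjusted over the list alone, 2 endothelial genes and 1 epithelial marker rose in the paired fit, and 0 in the unpaired fit. Vegfa, Kdr, Flt1, Hey1 and Bmp6 itself had log2 changes of 0.10, 0.07, 0.23, 0.03 and 0.05, none of which passed. Pdgfa missed the paired threshold, with 1 array left out at a time, without control replicate 2 (0.0883) or 4 h replicate 2 or 3 (0.0503 and 0.0514). Fgf2 missed it without 4 h replicate 3 (0.0543). Plk2 missed it without control replicate 2 (0.0768) or 4 h replicate 2 or 3 (0.0609 and 0.0584). Col4a1 missed it without control replicate 2 (0.0813) or 4 h replicate 2 (0.0815). Col4a2 missed it without control replicate 1 or 2 (0.0634 and 0.132), 4 h replicate 2 or 3 (0.137 and 0.103), 12 h replicate 2 or 3 (0.0508 and 0.0542) or 24 h replicate 3 (0.0551).

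After 12 h, Id2, Id1 and Id3 were up in the paired fit by 1.27, 0.97 and 0.79 on the log2 scale (paired SE 0.137, 0.097 and 0.08, n = 3 pairs, adjusted p 0.00658 each). Wnt2 rose by 0.96, Timp1 by 0.75, Tnfrsf12a by 0.65, Snai1 by 0.63, the small heat shock protein Cryab by 0.48, Cep295 by 0.44 and Lyar by 0.41 in the same fit. The interferon-inducible GTPase Tgtp1 fell by 1.21 on the log2 scale, the oxysterol hydroxylase Cyp39a1 by 0.89 and the leukocyte adhesion molecule Vcam1 by 0.80 (adjusted p 0.00658 each). Lbp, Mgst1, Adamts5, Gcnt1, Sema3c, Ephx1 and Adamts1 also fell in the paired fit, with changes from -0.79 to -0.62. Ptgs2 stood at 0.65 (paired adjusted p 0.163) and was higher in 2 of 3 pairs. None of the 32 named genes with a paired call at 12 h passed without 12 h replicate 2; for Id1, Id2, Id3, Tgtp1, Cyp39a1, Vcam1, Lbp and Adamts1 the adjusted p was then 0.0623, and of these only Id2 missed the threshold without another array, control replicate 2 (0.0542). Wnt2 missed the paired threshold with 1 array left out at a time, without control replicate 2 (0.0542) or 12 h replicate 1 or 2 (0.0632 and 0.087). Timp1 missed it without control replicate 2 (0.071) or 12 h replicate 1 or 2 (0.0535 and 0.0623). Sema3c missed it without control replicate 2 (0.055) or 12 h replicate 1 or 2 (0.0535 and 0.0698). Adamts5 missed it without control replicate 2 or 3 (0.148 and 0.0559) or 12 h replicate 1 or 2 (0.12 and 0.155). Tnfrsf12a missed it without control replicate 1 or 2 (0.0594 and 0.0988) or 12 h replicate 1 or 2 (0.112 and 0.153). Snai1 missed it without control replicate 1 or 2 (0.0984 and 0.217), 4 h replicate 1 or 2 (0.0501 and 0.0611), 12 h replicate 1, 2 or 3 (0.204, 0.186 and 0.084) or 24 h replicate 2 (0.0716). Mgst1 missed it without control replicate 1, 2 or 3 (0.0685, 0.071 and 0.0622), 12 h replicate 1, 2 or 3 (0.138, 0.148 and 0.0782) or 24 h replicate 3 (0.0592). Gcnt1 missed it without control replicate 1, 2 or 3 (0.0753, 0.158 and 0.0622), 4 h replicate 1 (0.0501), 12 h replicate 1 or 2 (0.138 and 0.155) or 24 h replicate 3 (0.0595). Ephx1 missed it without control replicate 1, 2 or 3 (0.0649, 0.0988 and 0.0581), 4 h replicate 2 (0.0523), 12 h replicate 1, 2 or 3 (0.0535, 0.179 and 0.132) or 24 h replicate 1 or 2 (0.0579 and 0.0514). Cryab missed it without control replicate 1 or 2 (0.0984 and 0.191), 4 h replicate 2 (0.0523), 12 h replicate 1, 2 or 3 (0.139, 0.186 and 0.123) or 24 h replicate 1, 2 or 3 (0.0622, 0.0692 and 0.0684). Cep295 missed it without control replicate 1, 2 or 3 (0.054, 0.235 and 0.089), 4 h replicate 2 or 3 (0.072 and 0.0531), 12 h replicate 1, 2 or 3 (0.222, 0.155 and 0.203) or 24 h replicate 1, 2 or 3 (0.0829, 0.0893 and 0.0826). Lyar missed it without control replicate 1 or 2 (0.101 and 0.238), 4 h replicate 1 or 2 (0.0761 and 0.0713), 12 h replicate 1, 2 or 3 (0.24, 0.236 and 0.128) or 24 h replicate 1, 2 or 3 (0.0643, 0.0893 and 0.0809). Under quantile normalization Cyp39a1 passed unpaired at -0.85 (0.0288).

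In the unpaired fit, 0 of 20280 probes passed at 12 h and 631 had an unadjusted p under 0.05 (2295 paired). The methods' t-test called 556 unadjusted and 0 adjusted. The genes with the smallest unadjusted p, none of which passed, were Id2, Wnt2, Timp1, Hbegf at 0.47 and Tnfrsf12a among the higher ones, and Cyp39a1, Sema3c, Tgtp1, Mxra8 at -0.44 and Clca3a1 at -0.51 among the lower ones. The paired fit called 109 probes, 27 higher and 82 lower. That count was 0 without 12 h replicate 2, 14 without control replicate 2, 17 and 26 without 12 h replicates 1 and 3, 37, 39 and 51 without 24 h replicates 3, 2 and 1, 51 and 70 without 4 h replicates 2 and 1, and 62 without control replicate 1. Without all 4 arrays of replicate 1, 2 or 3 it was 1, 1 and 0.

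At 12 h the BMP target list had a mean of 0.25 and a median of 0.063 over 15 members, of which 9 were above control and 4, Id1, Id2, Id3 and Snai1, rose in the paired fit (camera adjusted p 0.00306; adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, 4 rose in each fit. Prostanoid genes averaged 0.11 (median 0.055), with 11 of 12 above control and none passing over all genes (0.0336; adjusted p = 0.197 with an estimated correlation). Heat shock and oxidative stress genes averaged 0.10, with a median of 0.048 (0.00826; adjusted p = 0.464 with an estimated correlation) and cell division genes 0.08 (0.00717; adjusted p = 0.661 with an estimated correlation). Cholesterol synthesis genes averaged -0.11, with Fdft1 falling in the paired fit by 0.30 (0.00432; adjusted p = 0.464 with an estimated correlation). Glycolysis and hypoxia genes averaged -0.10 (median -0.059), with 14 of 17 lower (0.00677; adjusted p = 0.159 with an estimated correlation). Fibroblast markers averaged -0.11, with Prrx1 falling in the paired fit by 0.49 on the log2 scale (0.0334; adjusted p = 0.530 with an estimated correlation). The p53 list averaged -0.08, with a median of -0.051 (0.0339; adjusted p = 0.224 with an estimated correlation) and the interferon list -0.07 (0.0313; adjusted p = 0.224 with an estimated correlation). The interferon list missed the threshold in the paired fit (0.0533), where oxidative phosphorylation genes passed instead at -0.05 (0.0493; adjusted p = 0.685 with an estimated correlation). After quantile normalization the fibroblast and interferon lists missed it (0.0647 and 0.0604). Adjusted over the list alone in the paired fit, 2 prostanoid genes, 4 heat shock and oxidative stress genes and 1 cell division gene rose, and 3 cholesterol, 4 glycolysis, 2 fibroblast and 3 p53 genes fell, against 2 fibroblast genes and 0 of the others unpaired. In lists that did not pass, that paired count was 1 higher and 3 lower for angiogenic factors, 4 and 4 for matrix genes, 1 and 1 for BMP and TGF-beta mediators, 1 and 1 for the Wnt list, 1 and 2 for the unfolded protein list, 2 and 0 for smooth muscle genes and 0 and 1 for cytokine genes; unpaired, 1 matrix gene and 1 Wnt gene rose. In lists that did not pass, Vegfd and the Wnt target Ccn4 fell in the paired fit besides the genes named above. Vegfd missed the paired threshold, with 1 array left out at a time, without control replicate 1 or 2 (0.0535 and 0.133) or 12 h replicate 1, 2 or 3 (0.116, 0.155 and 0.0517). Ccn4 missed it without control replicate 1 or 2 (0.0535 and 0.0831) or 12 h replicate 1, 2 or 3 (0.105, 0.148 and 0.0714). The paired oxidative phosphorylation call ended without control replicate 3 (0.662, with the mean turned to 0.03), 4 h replicate 1 (0.0516), 12 h replicate 1 or 3 (0.213 and 0.199) or 24 h replicate 3 (0.0533). Mean and median differed in sign for immediate early genes (0.004 and -0.017), the unfolded protein response (0.004 and -0.004) and the Wnt list (0.008 and -0.019). The BMP target list passed without each array in turn. Leaving out control replicate 1 ended the calls of fibroblast markers (0.373), heat shock and oxidative stress (0.373), interferon response (0.146) and prostanoid genes (0.0861). Without control replicate 2 the lists that missed the threshold were cell division (0.52), cholesterol synthesis (0.195), heat shock and oxidative stress (0.153), interferon response (0.149), p53 response (0.149) and prostanoid genes (0.153). Leaving out control replicate 3 ended the calls of cholesterol synthesis (0.0988), fibroblast markers (0.155), glycolysis and hypoxia (0.17), interferon response (0.0533), p53 response (0.308) and prostanoid genes (0.0723). Without 12 h replicate 1 the lists that missed the threshold were cell division (0.726), cholesterol synthesis (0.0811), interferon response (0.0736) and p53 response (0.19). Leaving out 12 h replicate 2 ended the calls of fibroblast markers (0.338), interferon response (0.153) and prostanoid genes (0.0794). Without 12 h replicate 3 the lists that missed the threshold were fibroblast markers (0.114), heat shock and oxidative stress (0.155) and prostanoid genes (0.0863). Fdft1 missed the paired threshold with 1 array left out at a time, without control replicate 1, 2 or 3 (0.0907, 0.179 and 0.0544), 4 h replicate 1 or 2 (0.0542 and 0.0617), 12 h replicate 1, 2 or 3 (0.212, 0.186 and 0.106) or 24 h replicate 1, 2 or 3 (0.06, 0.0716 and 0.0592). Prrx1 missed it without control replicate 1 or 2 (0.116 and 0.238), 4 h replicate 1, 2 or 3 (0.0709, 0.0716 and 0.0645), 12 h replicate 1 or 2 (0.214 and 0.215) or 24 h replicate 1, 2 or 3 (0.0741, 0.0805 and 0.0809). Cell division genes averaged 0.021 without control replicate 2, 0.129 without control replicate 3, 0.015 without 12 h replicate 1 and 0.155 without 12 h replicate 2. Heat shock genes averaged 0.046 without control replicate 1, 0.053 without control replicate 2, 0.196 without control replicate 3 and 0.059 without 12 h replicate 3. Cholesterol genes averaged -0.201 without control replicate 1, -0.058 without control replicate 2 and -0.066 without 12 h replicate 1. Fibroblast markers averaged -0.024 without control replicate 1, -0.183 without control replicate 2, -0.194 without 12 h replicate 1 and -0.04 without 12 h replicate 2. Glycolysis genes averaged -0.055 without control replicate 3. Genes of the p53 list averaged -0.05 without control replicate 3. Interferon genes averaged -0.043 without 12 h replicate 2 and -0.102 without 12 h replicate 3. Oxidative phosphorylation genes averaged, in the paired fit, -0.079 without control replicate 1, -0.095 without control replicate 2, 0.03 without control replicate 3 and -0.078 without 12 h replicate 2.

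After 24 h, Id2 rose by 1.19 (paired SE 0.137, adjusted p 0.0295), Id1 by 1.07 (0.097, 0.00639) and Id3 by 0.92 (0.08, 0.00639) in the paired fit. The growth arrest gene Gas1 fell by 0.56 on the log2 scale (paired SE 0.062, adjusted p 0.0285), and was lower in 3 of 3 pairs. These 4 genes were the only ones whose probes passed. Ptgs2 stood at 0.30 (paired adjusted p 0.718). Id1 missed the paired threshold with 1 array left out at a time, without control replicate 1 (0.0701) or 24 h replicate 1 or 2 (0.0726 and 0.08). Id3 missed it without control replicate 1 or 2 (0.0701 and 0.0548) or 24 h replicate 2 (0.08). Id2 missed it without control replicate 1 or 2 (0.157 and 0.165), 4 h replicate 2 (0.0692), 12 h replicate 2 or 3 (0.0744 and 0.0542) or 24 h replicate 1, 2 or 3 (0.114, 0.242 and 0.243). Gas1 missed it without control replicate 1, 2 or 3 (0.157, 0.101 and 0.105), 12 h replicate 2 or 3 (0.074 and 0.0542) or 24 h replicate 1, 2 or 3 (0.12, 0.235 and 0.243).

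The unpaired fit called 0 probes at 24 h and 378 had an unadjusted p under 0.05 (1537 paired). The methods' t-test called 369 unadjusted and 0 adjusted. The genes with the smallest unadjusted p, none of which passed, were Id1, Id2, Id3, Cobl at 0.90 and Ube2h at 0.31 among the higher ones, and B3gnt5 at -0.56, Clca3a1 at -0.42, Sema3c at -0.54, Alx1 at -0.90 and Dusp26 at -0.48 among the lower ones. The paired count of 4 was 0 without control replicate 1 or 24 h replicate 2, 1 without 24 h replicate 1, and 2 without control replicate 2, 12 h replicate 2 or 3, or 24 h replicate 3. It was also 0 without all 4 arrays of any 1 replicate number. Under quantile normalization the paired calls were 4 higher and 0 lower.

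The BMP target list at 24 h had a mean of 0.24 and a median of 0.04, with 11 of 15 members above control and 3 rising in the paired fit (camera adjusted p 0.00306; adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell in each fit, and 1 cholesterol gene and 2 matrix genes fell in the paired fit by that count. In the same count 1 smooth muscle gene rose, and 2 Wnt genes rose and 1 fell, against 1 Wnt gene that rose unpaired. Unfolded protein response genes averaged -0.10, with 12 of 14 lower (0.0193; adjusted p = 0.464 with an estimated correlation), and ribosomal protein genes -0.13 (0.0156; adjusted p = 0.661 with an estimated correlation). Without control replicate 3 the ribosomal mean was 0.10 in the unpaired fit, and without 24 h replicate 2 it was 0.04. The paired mean was then -0.006 and -0.091 (adjusted p 0.647 and 0.0341), so its sign did not turn in that fit. Cartilage and bone genes averaged -0.14 over 7 members (0.0321; adjusted p = 0.197 with an estimated correlation) and cholesterol synthesis genes -0.08 (0.0223; adjusted p = 0.649 with an estimated correlation). Endothelial identity genes averaged -0.09, with 11 of 13 lower (0.0339; adjusted p = 0.224 with an estimated correlation), and Pecam1 stood at -0.38 without passing. Blood cell markers averaged -0.12 (median -0.073), with 7 of 8 lower (0.0108; adjusted p = 0.169 with an estimated correlation). The paired fit added prostanoid genes at 0.08 (0.0435; adjusted p = 0.273 with an estimated correlation) and matrix genes at -0.05 (0.00613; adjusted p = 0.288 with an estimated correlation). The paired prostanoid call ended without control replicate 1, 2 or 3 (0.0884, 0.159 and 0.0549), 4 h replicate 3 (0.0511), 12 h replicate 1 (0.0516) or 24 h replicate 1 or 3 (0.0628 and 0.144), and that of matrix genes without control replicate 2 (0.0595) or 24 h replicate 2 (0.0938). Quantile normalization ended the endothelial, cholesterol and ribosomal calls (0.324, 0.0713 and 0.0802), and brought in the prostanoid list (0.015) and cell division genes at 0.05 (0.032). As deposited, unpaired camera gave these 2 lists adjusted p of 0.0682 and 0.633, and adjusted p = 0.224 and 0.934 with an estimated correlation. Leaving out control replicate 1 ended the calls of blood cell markers (0.0867), cartilage and bone (0.0683), endothelial identity (0.142) and unfolded protein response (0.373). Without control replicate 2 the lists that missed the threshold were BMP targets (0.0798), blood cell markers (0.218), cartilage and bone (0.152), cholesterol synthesis (0.585) and endothelial identity (0.376). Leaving out control replicate 3 ended the calls of cartilage and bone (0.193), cholesterol synthesis (0.277), ribosomal proteins (0.308) and unfolded protein response (0.318). Without 24 h replicate 1 the lists that missed the threshold were cholesterol synthesis (0.526) and ribosomal proteins (0.0518). Leaving out 24 h replicate 2 ended the calls of cartilage and bone (0.0674), endothelial identity (0.428), ribosomal proteins (0.785) and unfolded protein response (0.291). Without 24 h replicate 3 the lists that missed the threshold were cartilage and bone (0.0649) and unfolded protein response (0.0708). Mean and median differed in sign for the Wnt list (-0.001 and 0.001). Over the 3 times 29 of 75 list tests passed, and 12, 15 and 14 passed without control replicates 1, 2 and 3. Cholesterol genes averaged -0.166 without control replicate 1, -0.023 without control replicate 2, -0.043 without control replicate 3 and -0.025 without 24 h replicate 1. Unfolded protein genes averaged -0.057 without control replicate 1, -0.188 without control replicate 2, -0.054 without control replicate 3, -0.153 without 24 h replicate 1 and -0.055 without 24 h replicate 2. Endothelial genes averaged -0.042 without 24 h replicate 2. Blood cell markers averaged -0.068 without 24 h replicate 2. Ribosomal genes averaged -0.325 without control replicate 2 and -0.294 without 24 h replicate 3. Matrix genes averaged, in the paired fit, -0.028 without 24 h replicate 2.

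By fry, which does not compare a list with other genes, BMP targets moved on balance one way, upward, in the paired fit at 4, 12 and 24 h (adjusted p 0.00296, 0.00347 and 0.00347), and in the unpaired fit passed at 4 h but not at 12 or 24 h (0.0395, 0.0946 and 0.0946). Prostanoid genes moved upward by the same test at each time, with adjusted p of 0.00189, 0.00581 and 0.0239 unpaired and 0.000614, 0.00149 and 0.00396 paired. At 4 h the paired test also called cytokine genes (0.00149; 0.15 unpaired), smooth muscle genes (0.0105; 0.34) and immediate early genes (0.0225; 0.0946) upward and cholesterol genes downward (0.0294; 0.576). At 12 h it called the p53 list (0.0284; 0.329) and cholesterol genes (0.0431; 0.576) downward. The other lists did not pass it in either fit with all arrays. Paired calls of BMP targets and prostanoid genes at the 3 times and of cytokine genes at 4 h passed without each array in turn, as did the unpaired call of prostanoid genes at 4 h. The unpaired BMP target call at 4 h ended without control replicate 1 or 2 (0.0626 and 0.148), 4 h replicate 1, 2 or 3 (0.15, 0.129 and 0.0539), 12 h replicate 2 or 3 (0.0572 and 0.0833) or 24 h replicate 1, 2 or 3 (0.0616, 0.0601 and 0.0725). Unpaired prostanoid calls ended at 12 h without control replicate 1 (0.0626) or 12 h replicate 3 (0.0833), and at 24 h without control replicate 1 or 2 (0.166 and 0.199), 4 h replicate 1 (0.0609), 12 h replicate 3 (0.0833) or 24 h replicate 2 or 3 (0.0601 and 0.143). Among paired calls at 4 h, that of smooth muscle genes ended without control replicate 2 (0.051) or 4 h replicate 2 (0.0542). Immediate early genes missed the threshold of fry without control replicate 1 or 2 (0.0911 and 0.0905), 4 h replicate 1 or 2 (0.0968 and 0.0712), 12 h replicate 1, 2 or 3 (0.0553, 0.0533 and 0.0527) or 24 h replicate 1 or 2 (0.06 and 0.0548). Cholesterol genes missed it at 4 h without control replicate 2 or 3 (0.103 and 0.094), 4 h replicate 1, 2 or 3 (0.0704, 0.0736 and 0.0786), 12 h replicate 1, 2 or 3 (0.0554, 0.0533 and 0.0664) or 24 h replicate 1, 2 or 3 (0.06, 0.0548 and 0.0629), and at 12 h without control replicate 2 or 3 (0.177 and 0.116), 4 h replicate 1 or 2 (0.0792 and 0.0736), 12 h replicate 1, 2 or 3 (0.0754, 0.195 and 0.118) or 24 h replicate 1, 2 or 3 (0.0714, 0.07 and 0.0761). The p53 list missed it without control replicate 2 or 3 (0.103 and 0.0519), 4 h replicate 1 or 2 (0.0571 and 0.0542), 12 h replicate 1, 2 or 3 (0.0868, 0.155 and 0.0566) or 24 h replicate 1 or 2 (0.0566 and 0.0548).

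Between 4 and 24 h, Tnfrsf12a fell by 0.97 on the log2 scale (n = 3 per group, adjusted p 0.0117 unpaired, 0.00389 paired), Hbegf by 0.76 (0.0332, 0.0078) and Ccn2 by 1.55 (0.0424, 0.0108). Cavin2 rose by 0.88 (0.0424, 0.00735) and the ubiquitin-conjugating enzyme Ube2h by 0.52 (0.0424, 0.0078). Ptgs2 fell by 1.05 in the paired fit (adjusted p 0.0213; 0.115 unpaired), and Dusp6, Hmox1 and Txnrd1 fell there too, by 0.80, 0.72 and 0.72. Id1, Id2 and Id3 differed by 0.10, 0.34 and 0.28 between 4 and 24 h, and none of them passed in the paired fit (adjusted p 0.726, 0.274 and 0.124). The unpaired fit called 7 probes, 2 higher and 5 lower at 24 h, with 1103 at an unadjusted p under 0.05, the methods' t-test called 1133 unadjusted and 1 after adjustment, and all 7 were among the 420 of the paired fit, 195 higher and 225 lower. The unpaired count was 0 without any single 24 h array or without 4 h replicate 2 or 3, 1 without control replicate 2, 3 without control replicate 1 or 12 h replicate 1 or 2, 4 without 12 h replicate 3 and 12 without 4 h replicate 1; the paired count was 21, 42 and 71 without 24 h replicates 2, 3 and 1, 37 and 47 without 4 h replicates 2 and 3, 224 and 267 without 12 h replicates 3 and 1, and 264 without control replicate 2. Without all 4 arrays of replicate 1, 2 or 3 the paired count was 140, 0 and 0. Quantile normalization and centring left 6 and 4 unpaired calls, all lower at 24 h. With 1 array left out at a time, the unpaired adjusted p missed the threshold for Tnfrsf12a without 4 h replicate 2 or 3 (0.104 and 0.0879) or 24 h replicate 1, 2 or 3 (0.1, 0.091 and 0.0625). For Hbegf it missed without control replicate 1 or 2 (0.0763 and 0.0528), 4 h replicate 2 or 3 (0.166 and 0.182), 12 h replicate 1, 2 or 3 (0.0669, 0.0519 and 0.0516) or 24 h replicate 1, 2 or 3 (0.199, 0.197 and 0.171). For Ccn2 it missed without control replicate 1, 2 or 3 (0.0927, 0.0708 and 0.0637), 4 h replicate 1, 2 or 3 (0.0878, 0.233 and 0.0879), 12 h replicate 3 (0.0704) or 24 h replicate 1, 2 or 3 (0.199, 0.216 and 0.235). For Cavin2 it missed without control replicate 1 or 2 (0.0927 and 0.0626), 4 h replicate 2 or 3 (0.208 and 0.253), 12 h replicate 1, 2 or 3 (0.0777, 0.0779 and 0.0754) or 24 h replicate 1, 2 or 3 (0.199, 0.216 and 0.242). For Ube2h it missed without control replicate 1 or 2 (0.0927 and 0.0626), 4 h replicate 1, 2 or 3 (0.0878, 0.333 and 0.228), 12 h replicate 1, 2 or 3 (0.0777, 0.0519 and 0.0704) or 24 h replicate 1, 2 or 3 (0.199, 0.197 and 0.246). The paired call of Tnfrsf12a passed without each array in turn. Hbegf missed the paired threshold without 24 h replicate 2 or 3 (0.0612 and 0.0506). Ccn2 missed it without 4 h replicate 2 (0.0755) or 24 h replicate 2 or 3 (0.0743 and 0.0594). Cavin2 missed it without 24 h replicate 2 or 3 (0.0592 and 0.0506). Ube2h missed it without 4 h replicate 2 (0.0592) or 24 h replicate 2 or 3 (0.0592 and 0.0592). Ptgs2 missed it without 4 h replicate 2 or 3 (0.0995 and 0.112) or 24 h replicate 1, 2 or 3 (0.0792, 0.0998 and 0.11). Dusp6 missed it without 24 h replicate 2 or 3 (0.0595 and 0.0506). Hmox1 missed it without 4 h replicate 2 (0.0541) or 24 h replicate 2 or 3 (0.0571 and 0.0506). Txnrd1 missed it without 4 h replicate 2 or 3 (0.0771 and 0.0707) or 24 h replicate 1, 2 or 3 (0.0794, 0.0571 and 0.092).

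From 4 to 12 h, Ccn2 fell by 1.38 on the log2 scale among the probes called by the paired fit, and Vcam1 by 0.70, Hmox1 by 0.64 and both probes of Vcl by 0.80 and 0.73. The integrin chain Itga5 fell by 0.56 and the actin regulator Mical2 by 0.67 and 0.43 on its probes, and Cavin2 rose by 0.69. These genes were named after their values were seen. The unpaired fit called 0 probes, with 614 at an unadjusted p under 0.05, and the methods' t-test 805 unadjusted and 0 adjusted. The paired fit called 20, 1 higher and 19 lower at 12 h. That count was 123 without 4 h replicate 1, 0 without 4 h replicate 2 or 3 or 12 h replicate 2, 1 without 12 h replicate 3, 6, 7 and 10 without 24 h replicates 2, 3 and 1, 8 without control replicate 1, and 12 without control replicate 2 or 12 h replicate 1. The count was also 0 without all 4 arrays of any 1 replicate number. With 1 array left out at a time, the probe of Ccn2 missed the paired threshold without control replicate 1 or 3 (0.0628 and 0.0524), 4 h replicate 1, 2 or 3 (0.0503, 0.275 and 0.127), 12 h replicate 1, 2 or 3 (0.12, 0.0651 and 0.267) or 24 h replicate 1, 2 or 3 (0.0843, 0.073 and 0.0983). Vcam1 missed it without 4 h replicate 2 or 3 (0.15 and 0.0522) or 12 h replicate 2 (0.0917). Hmox1 missed it without control replicate 1 (0.0568), 4 h replicate 2 or 3 (0.274 and 0.166), 12 h replicate 2 or 3 (0.199 and 0.267) or 24 h replicate 1, 2 or 3 (0.0659, 0.073 and 0.0625). The Vcl probe at -0.80 missed it without control replicate 1 (0.0568), 4 h replicate 2 or 3 (0.206 and 0.166), 12 h replicate 2 or 3 (0.142 and 0.156) or 24 h replicate 2 or 3 (0.0718 and 0.0625). The Vcl probe at -0.73 missed it without control replicate 1 or 2 (0.0628 and 0.08), 4 h replicate 2 or 3 (0.275 and 0.166), 12 h replicate 1, 2 or 3 (0.0796, 0.221 and 0.27) or 24 h replicate 1, 2 or 3 (0.0884, 0.088 and 0.0983). Itga5 missed it without 4 h replicate 2 or 3 (0.103 and 0.0522) or 12 h replicate 2 or 3 (0.0651 and 0.0699). The Mical2 probe at -0.67 missed it without 4 h replicate 2 or 3 (0.0886 and 0.0522) or 12 h replicate 2 or 3 (0.0651 and 0.0699). The Mical2 probe at -0.43 missed it without control replicate 1, 2 or 3 (0.0628, 0.0836 and 0.0524), 4 h replicate 2 or 3 (0.275 and 0.166), 12 h replicate 1, 2 or 3 (0.116, 0.221 and 0.289) or 24 h replicate 1, 2 or 3 (0.0884, 0.073 and 0.0983). Cavin2 missed it without control replicate 1, 2 or 3 (0.0628, 0.0836 and 0.0524), 4 h replicate 2 or 3 (0.275 and 0.227), 12 h replicate 1, 2 or 3 (0.151, 0.223 and 0.267) or 24 h replicate 1, 2 or 3 (0.0843, 0.0821 and 0.0983).

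From 12 to 24 h, the chaperone Hspa5 fell by 0.78 on the 1 of its 3 probes that passed, and Cyp39a1 and Vcam1 rose by 0.78 and 0.67, in the paired fit among probes (adjusted p 0.0377, 0.0411 and 0.0377). The other Hspa5 probes fell too, from 0.481 to -0.282 and from 0.367 to -0.338 against control, without passing. These genes were named after their values were seen, and with probes of a gene averaged 0 passed. The unpaired fit called 0 probes, with 312 at an unadjusted p under 0.05, and the methods' t-test 468 unadjusted and 0 adjusted. Under quantile normalization 5 were higher and 3 lower, against 3 and 1 as deposited. The 4 paired calls were 4 in number only without 4 h replicate 2; 1 passed without 12 h replicate 3 and 0 without any other single array. Without all 4 arrays of any 1 replicate number 0 passed. Hspa5 missed the threshold without control replicate 1, 2 or 3 (0.0814, 0.0782 and 0.0613), 4 h replicate 1 or 3 (0.0909 and 0.0721), 12 h replicate 1, 2 or 3 (0.1, 0.298 and 0.125) or 24 h replicate 1, 2 or 3 (0.324, 0.0958 and 0.291). Cyp39a1 missed it without control replicate 1, 2 or 3 (0.0814, 0.0782 and 0.0777), 4 h replicate 1 or 3 (0.0909 and 0.0721), 12 h replicate 1, 2 or 3 (0.175, 0.3 and 0.125) or 24 h replicate 1, 2 or 3 (0.324, 0.0895 and 0.291). Vcam1 missed it without control replicate 1, 2 or 3 (0.0814, 0.0782 and 0.0668), 4 h replicate 1 or 3 (0.0909 and 0.0721), 12 h replicate 1 or 2 (0.175 and 0.298) or 24 h replicate 1, 2 or 3 (0.324, 0.163 and 0.291).

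Over the 3 times together, the unpaired F test called 4 probes: those of Tnfrsf12a, Cavin2 and Hbegf (adjusted p 0.0101, 0.026 and 0.026) and an unnamed one. The paired F test called 333. The unpaired count was 0 without control replicate 1 or 2 or 4 h replicate 2 or 3, 1 without 12 h replicate 1 or any single 24 h array, 2 without 12 h replicate 2, 8 without 4 h replicate 1 and 10 without control replicate 3; the paired count was 71 and 89 without 4 h replicates 2 and 3, 119, 123 and 162 without 24 h replicates 3, 2 and 1, 120 without control replicate 2, and 136, 156 and 190 without 12 h replicates 2, 3 and 1. Without all 4 arrays of replicate 1, 2 or 3 the paired count was 47, 0 and 0.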

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

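The tests of the spot order, of the numbering, of the batch labels, of time in culture and of Id1, Id2 and Id3 over time were chosen after the values they use had been seen, and the list tests within replicate numbers after those over all 12 arrays. The other tests in this part were set before their results were seen.

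Changes that differed between 4 and 24 h by a test of the difference, in the unpaired fit, were those of Cavin2 (24 h minus 4 h 0.88 on the log2 scale), Ube2h (0.52), Tnfrsf12a (-0.97), Hbegf (-0.76) and Ccn2 (-1.55). In all, 7 probes differed between these times. Of the 12 arrays, leaving out any 1 of 5 ended the call of Tnfrsf12a, any 1 of 10 that of Hbegf, any 1 of 10 that of Ccn2, any 1 of 10 that of Cavin2 and any 1 of 11 that of Ube2h.

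More probes were called at 4 h than at 24 h. In the paired fit with probes averaged per gene, 423 genes other than Id1, Id2 and Id3 passed at 4 h. By 24 h, 416 of them (98.3%) had moved against the direction of their 4 h change, toward control or past it. Because these genes were chosen for a large value at 4 h, some return is built in. A stronger response of all genes on the 4 h arrays would have Id1, Id2 and Id3 fall too. They were instead higher at 24 h than at 4 h by a mean of 0.241 (SD over pairs 0.16, from 0.086 to 0.405). None of them passed in that comparison in the paired fit, and they were picked after their values were seen. The explanation therefore stays open for the other genes. One deviating 4 h array is argued against by the paired count at 4 h, at least 149 without each 4 h array in turn, above the 109 called at 12 h. Time in culture stays open and cannot be told apart from time with BMP6, because the 3 control arrays form 1 group with no time; a transient early response is a hypothesis that these data leave untested.

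Arrays with the same replicate number deviated together. Among all ways to number the arrays, 1, the real one, gave a mean correlation as high as 0.586, and the next gave 0.36, which argues against arbitrary numbers. Array-wide distributions were already nearly equal, so quantile normalization, which left 52.67% of the sum of squares between numbers, could not test them. A shared culture, day or hybridisation batch may lie behind the numbers and stays open, since 0 labels name one. No biological explanation was tested.

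Probes of a gene did not correlate at the deposited row numbers. A different order of the spots would give agreement in some reading of the grid, and one reading gave r = 0.471. An annotation that names the wrong genes is argued against by r of at least 0.397 on each array in that reading. How the orders came to differ was not tested, and no biological explanation applies. With the deposited row numbers, 0 of 75 list tests passed, against 29 in the recovered order.

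For the contrasts of 3 arrays with 3, the 10 splits are too few for a share under 0.05. At 4 h the real split called 20 probes and the highest of the others 0 (1 split of 10 with as many). Between 24 and 4 h it called 7 against 0 (1 of 10). At 12 h, between 12 and 4 h and between 24 and 12 h every split called 0, so that 10 of 10 gave as many; at 24 h the real split called 0 and the highest other 1 (10 of 10). In the paired fit, the 4 splits that exchange at most 1 pair are also too few: the real counts were 548, 109, 4, 20, 4 and 420, and each other split called 0. For the F test over the 3 times, 3 of 100 drawn splits of the 12 arrays called at least as many as the real 4, a share under 0.05. The others of these called 527 and 1027 probes and put 5 and 8 pairs of same-numbered arrays in one group, where the real split puts 0, which points to the structure by replicate number. In the paired fit, 1 of 100 splits within replicate numbers gave as many as the real 333, with 21 the highest of the others, so chance assignment is unlikely to give that many. For the list tests, 1 of 100 splits gave as many as the real 29, with a median of 12 and at most 24 in the others. These splits ignore the replicate numbers. Among 100 splits within replicate numbers, 2 gave as many as the real 29 in the unpaired fit, with a median of 10 and at most 30 in the others. Paired, 1 gave as many as the real 30, with a median of 12 and at most 27 in the others. Each share is under 0.05, so chance assignment seldom gave so many, but it is not excluded: the highest other unpaired split gave 30. Splits that only rename the real groups were left out. Nothing follows for any single list. With an estimated correlation 0 of 75 tests passed in either fit, so these calls rest on the preset one. Whether that explains passes under other groupings was not tested.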

How the results depend on the processing

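Alternatives for the paired fit and the deposited order were chosen after seeing the data. Counts are given in the order 4 h, 12 h, 24 h, 12 h against 4 h, 24 h against 12 h, 24 h against 4 h, any time. Except where stated, the cause was not tested. No spot signal over background was used, so what dim probes limit is unknown. Leaving out an array leaves its group with 2.

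From the unpaired counts of 20, 0, 0, 0, 0, 7 and 4, the replicate block gave 548, 109, 4, 20, 4, 420 and 333. Quantile normalization gave 1 at 12 h, and centring gave 4 for 24 h against 4 h. Array weights gave 37 at 4 h, 10 for 12 h against 4 h, 68 for 24 h against 4 h and 31 at any time. A trend with robust variance gave 10 at 4 h and averaging probes 12. Fitting only the groups compared gave 0 at 4 h and 0 for 24 h against 4 h, with fewer arrays for the spread. The methods' t-test unadjusted gave 864, 556, 369, 805, 468 and 1133, and adjusted 0 at 4 h and 1 for 24 h against 4 h. Leaving out 1 array gave 3 to 23, 0 to 0, 0 to 0, 0 to 0, 0 to 0, 0 to 12 and 0 to 10. A filter for values on all arrays removed nothing.

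From the paired counts, dropping the replicate block gave 20, 0, 0, 0, 0, 7 and 4. Quantile normalization gave 9 for 12 h against 4 h and 8 for 24 h against 12 h, and centring 9 for 12 h against 4 h. Array weights, whose estimation stopped before reaching its tolerance, gave 166 at 12 h, 7 at 24 h, 179, 44, 793 and 673. A trend with robust variance and averaging probes each gave 0 for 24 h against 12 h. A minimum of 1.5-fold, which only removes calls, gave 75, 28, 12 for 12 h against 4 h, 60 for 24 h against 4 h and 83 at any time. Fitting only the groups compared gave 61, 1, 0 and 0 between neighbouring times and 68. Leaving out 1 array or the 4 arrays of a replicate number gave 0 to 745, 0 to 162, 0 to 6, 0 to 123, 0 to 4, 0 to 548 and 0 to 385. Without the 4 arrays of replicate 1, 2 or 3 the count at 4 h was 314, 0 and 44.

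Of the 29 list tests, 0 passed with an estimated correlation and 0 with gene names at the deposited row numbers; 12 to 31 passed with 1 array left out. In the unpaired fit, ribosomal protein genes reversed at 4, 12 and 24 h without control replicate 3 (0.068, 0.22 and 0.096) and at 24 h without 24 h replicate 2 (0.042), and oxidative phosphorylation genes at 4 h without control replicate 3 (0.016) and at 24 h without 24 h replicate 2 (0.105). Paired, without control replicate 3, the ribosomal values were -0.034, 0.119 and -0.006, so that those at 4 and 24 h kept their sign, and the oxidative phosphorylation values -0.042, 0.03 and 0.048, a reversal of the paired call at 12 h. Without 24 h replicate 2 the paired values at 24 h were -0.091 and 0.001. At the deposited row numbers, Hbegf, Prkcd, Tnfrsf12a and Wnt2 reversed at 4 h (-0.156, -0.034, -0.098 and -0.048). Without control replicate 2 the ribosomal values were -0.354, -0.201 and -0.325 at 4, 12 and 24 h, and those of oxidative phosphorylation -0.267 at 4 h and -0.177 at 24 h, against 0.106 at 24 h without control replicate 3. Among values not called in either setting, 253 signs changed in 6540 comparisons. The replicate block changed no list call other than those given above. The median level of liver, testis and brain markers was -1.615 as deposited and -1.548 centred.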

Other observations

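The Armcx tests here were chosen after the values had been seen. Of the Armcx genes, a family of X-linked armadillo-repeat genes, 5 were measured. The 3 that fell in the paired fit at 4 h lay closer to control later: Armcx2 stood at -0.50 at 12 h (paired adjusted p 0.00886) and -0.08 at 24 h, Armcx3 at -0.39 (0.0266) and -0.04, and Armcx6 at -0.30 (0.14) and -0.01. Between 4 and 24 h each rose in the paired fit (adjusted p 0.00154, 0.00247 and 0.00735). The 12 h paired calls of Armcx2 ended without control replicate 2 (0.0629) or 12 h replicate 1 or 2 (0.0535 and 0.0845), and of Armcx3 without control replicate 1 or 2 (0.0746 and 0.159), 4 h replicate 2 (0.0505), 12 h replicate 1 or 2 (0.152 and 0.163) or 24 h replicate 2 or 3 (0.0558 and 0.0593). The 24 against 4 h call of Armcx6 ended without 24 h replicate 2 or 3 (0.0571 and 0.0506).

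A hypothesis was that the family moves as a set. Armcx1 at -0.13 and Armcx4 at -0.01 had a mean log2 change of -0.067 at 4 h, at percentile 26.34 of 10000 random gene sets of the same size. These 2 are what was left after the 3 members with large falls had been set aside, so this value decides nothing and the hypothesis stays open. Whether probes of Armcx2, Armcx3 and Armcx6 bind each other's transcripts was not tested.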
